A study of Rattus norvegicus with 2 samples.

How the data were processed

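Whole carotid bodies of young adult wild-type Wistar rats kept for 8 days in normoxia or in hypoxia (10% oxygen) were dissociated with enzymes, and the cells were read with the 10x Genomics Chromium 3′ kit, version 3, on an Illumina sequencer, per the labels' protocols. The groups were taken from the treatment label, with 1 library each. The authors deposited for each library an unfiltered matrix of UMI counts per gene and barcode, with 23139 genes given by Ensembl identifier and symbol. The counts were made with Cell Ranger 7.0.1 per the submitters' processing notes, while the deposited matrices name software version Cell Ranger 4 per the file headers. The genome build, the annotation release and the treatment of intronic reads are not given in the sources used here. No cell calling, doublet call or cell annotation of the authors was used here.

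The cell filters, the doublet rate, the clustering settings, the markers, the gene lists and their minimums, the intervals, the rule for named genes and the alternatives listed first were chosen before the data were examined. The thresholds of the naming of clusters, the limit for empty droplets, the marker minimum of the free RNA estimate and the number of expression bins were set later. Barcodes with at least 1000 UMIs, at least 500 genes and at most 20% of UMIs from mitochondrial genes were called cells, which gave 10825 in normoxia and 40043 in hypoxia. Of the barcodes that passed both minimums, 164 of 10989 in normoxia and 716 of 40759 in hypoxia were over the mitochondrial limit. Doublets were scored with Scrublet in each library, and the barcodes with the highest scores were removed at 0.8% per 1000 called cells, that is 937 (8.66%) in normoxia and 12828 (32.0%) in hypoxia. The automatic threshold of Scrublet marked 750 (6.93%) and 154 barcodes (0.385%), and neither call was compared with known doublets. The removed share follows the number of called barcodes, and many shallow barcodes pass the UMI minimum in hypoxia, where those of clusters with markers of unrelated classes had a median of 1783 UMIs. The loading of the hypoxic channel is not given in the sources used here, so the true doublet rate is open, and 21 values turned without removal. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 gave 34 clusters over both libraries without integration. Kept cells held 73.5% of all UMIs in normoxia and 59.3% in hypoxia.

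Clusters were named from fixed markers of 25 cell classes, and a class is called X-like. A marker counted where its level in the cluster was at least 2 times its median over the clusters, with 20 CPM added to both, and at least 10% of the cluster's cells had a UMI. A name needed at least 3 markers, and among the 10 leading genes by fold no more markers of another class than of its own. A cluster whose median UMI count was under that of its library divided by 3, with none of its class's markers among these 10 genes, also stayed unnamed. After an earlier naming had been seen, 1 rule was added. It leaves unnamed a cluster with at least 3 markers and a share of at least 0.5 of the markers of a class outside its own family, and it decides the direction of the endothelium-like and fibroblast-like shares. Lymphatic endothelium-like cells (30 in normoxia and 67 in hypoxia) had fewer than the 50 cells in each library that a comparison required, and 7 classes were compared. Unnamed cells made up 25.0% of kept cells in normoxia and 59.8% in hypoxia, of which 3.83% and 44.5% of kept cells were unnamed by the added rule alone and 21.1% and 15.3% by the original rules. The original rules also left unnamed clusters 16, 17 and 28, which carried markers of unrelated classes. Clusters 2, 11 and 23 stayed unnamed for leading genes of another class. They carried 8 of 11 fibroblast, 6 of 6 pericyte and 10 of 10 blood endothelium markers. With 1104, 560 and 197 cells in normoxia and 1354, 702 and 135 in hypoxia, they are missing from all shares and values by class.

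UMIs were summed per class and library and given as CPM with exact Poisson intervals. The log2 of hypoxia over normoxia carries an exact binomial (Clopper-Pearson) interval of the split of UMIs between both libraries. All intervals are at the 95% level and cover counting error only. With 1 library per group there is no test between the conditions, no p-value was computed, and a difference compares these libraries. For each of 25 gene lists on oxygen sensing and metabolism, transmission, cell stress, immunity, glia and stem cells, niche signals, vessels and matrix, the median log2 of the members with at least 20 UMIs over both libraries was taken where at least 5 were measured. Its percentile among 10000 random lists of the same size, matched over 20 expression bins, describes these libraries only. Haemoglobin and other short lists had too few members for a median. Under most alternatives the minimum of 20 UMIs was applied anew to the changed sums, so a list can hold other members there.

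Genes were named by a fixed rule with 3 parts. It took 19 genes fixed by name, then up to 4 members per list with the largest absolute log2, then the 10 highest and the 10 lowest genes in glomus-like and in glia-like cells and the 5 highest and 5 lowest in the other classes. List members needed at least 30 UMIs and 50 CPM in the higher library. The last part also asked for a UMI in 10% of cells and a level at or above that of empty droplets, and left out mitochondrial, ribosomal and haemoglobin genes, genes without a symbol and markers of another class. The text gives a part of the genes so named, and some of them are not reported here. A gene with under 3 UMIs in a library would be given as a bound. Under the alternatives, subtraction of free RNA included, sums under 3 UMIs were also set to 3, and such values are not all marked.

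Empty droplets were barcodes with under 100 UMIs (1583007 with 2830973 UMIs in normoxia and 2064215 with 4533746 UMIs in hypoxia). The share of free RNA per class was estimated from the markers of other classes at 20 CPM or more. Some fixed markers are also members of the gene lists, so list medians after subtraction depend in part on this estimate. The estimated share was 2.93% in normoxia and 4.11% in hypoxia in glomus-like cells, 9.62% and 10.4% in glia-like, 5.60% and 6.08% in fibroblast-like, 4.57% and 6.65% in endothelium-like, 6.51% and 9.11% in smooth muscle-like, 4.35% and 6.89% in macrophage-like and 7.52% and 15.5% in Schwann-like cells. The median depth per cell was 13792 and 8062 UMIs in glomus-like, 3539 and 3032 in glia-like, 6773 and 5202 in fibroblast-like and 4020 and 2118 in Schwann-like cells. Intervals follow the UMIs summed per class. They are wide for Schwann-like cells, with 396326 UMIs in normoxia and 165747 in hypoxia. For abundant genes of the other classes named here they are narrow, with 5612978 and 4776675 UMIs in glia-like cells. To compare shares of cells with a cell-cycle UMI, cells were thinned to 1000 UMIs, a number set after the depths were seen. The share that free RNA alone would give was computed from the cell-cycle level of empty droplets and the estimated share of free RNA in the class.

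The scripts were tested on simulated data before use, with counts drawn for hypoxia over normoxia at the UMI totals of the called barcodes divided by 10. Over 23139 genes, intervals covered the truth for 95.6% of 13816 unchanged genes and for 97.1%, 90.9% and 97.0% of genes with an absolute log2 of 0.5, 1 and 2 (68, 66 and 66 genes). Of 200 lists of 15 members drawn from 14016 genes without a shift, 7% lay outside the central 95% of random lists, and 100% did with a shift of 0.5. A true free RNA share of 5% was estimated as 5.06% in normoxia and 4.97% in hypoxia, and 20% as 20.0% and 19.8%, over 23139 genes. The markers that the estimate reads were removed from the simulated class before free RNA was mixed in. This recovery was thus near certain, and a bias from native expression of such markers was not tested.

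The alternatives were UMI minimums of 500 and 2000, an order-of-magnitude minimum at the 99th percentile of the 3000 deepest barcodes divided by 10 (5724 UMIs in normoxia and 3976 in hypoxia), a mitochondrial limit of 10%, no doublet removal, the automatic Scrublet threshold, and resolutions of 0.5 and 2.0. Further ones were median ratio scaling, 1 UMI added, genes centred and scaled within each library before the principal components, totals without mitochondrial and ribosomal genes, the mean over cells of each cell's share, thinned cells, subtraction of the empty-droplet profile, no thinning, and other minimums for list members. Chosen after seeing the data were the mixed-profile clusters kept (those that the added rule alone left unnamed), glomus-like cells without cluster 14, cluster 14 alone, glia-like cells of cluster 5 alone, and macrophage-like cells of cluster 12 and of cluster 21 alone. Software was Python 3.11.15, scanpy 1.11.5 (with Scrublet), anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.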

Results

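The carotid body is a small chemoreceptor organ at the fork of the carotid artery. Its glomus cells sense the oxygen of arterial blood and release catecholamines and other transmitters, and its sustentacular glia-like cells hold a stem cell pool that was the subject of the series. Whole carotid bodies of young adult wild-type Wistar rats kept for 8 days in normal air or in 10% oxygen were dissociated, and single cells were read with 3′ droplet RNA sequencing. Each condition gave 1 library, so no difference between conditions has a replicate check, and the number of animals per library is not given in the sources used here. The normoxic library held 121230819 UMIs over 2189371 barcodes, and the hypoxic library 210227925 UMIs over 2743533 barcodes. After filtering and doublet removal, 9888 cells with a median of 6994 UMIs and 2666 genes remained in normoxia, and 27215 cells with a median of 3427 UMIs and 1659 genes remained in hypoxia. Intervals are 95% intervals, exact Poisson for sums of UMIs and exact Clopper-Pearson for shares and for the log2 of sums, and cover counting error only. Levels are CPM, the UMIs of a gene summed over the cells of a class and scaled by the UMI total of that class, and log2 values are hypoxia over normoxia.

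The main question of the design is how the cells of the organ differ after sustained hypoxia. Glomus-like, sustentacular glia-like, fibroblast-like, blood endothelium-like, smooth muscle-like, macrophage-like and myelinating Schwann-like cells were found in both libraries in numbers that allowed a comparison. Among the cells given a class, macrophage-like cells made up 4.92% (4.44 to 5.44) in normoxia and 11.2% (10.6 to 11.8) in hypoxia, and glomus-like cells 32.7% (31.6 to 33.8) and 37.7% (36.8 to 38.6). Sustentacular glia-like cells made up 18.9% (18.0 to 19.8) of the classed cells in normoxia and 12.9% (12.3 to 13.6) in hypoxia. Of all kept cells, the shares in normoxia and hypoxia were 24.5% (23.7 to 25.4) and 15.2% (14.7 to 15.6) for glomus-like, 14.2% (13.5 to 14.9) and 5.20% (4.94 to 5.47) for glia-like and 17.7% (17.0 to 18.5) and 9.06% (8.72 to 9.40) for fibroblast-like cells. They were 7.20% (6.70 to 7.73) and 3.40% (3.19 to 3.62) for endothelium-like, 6.44% (5.97 to 6.94) and 2.41% (2.23 to 2.60) for smooth muscle-like, 3.69% (3.33 to 4.08) and 4.49% (4.25 to 4.74) for macrophage-like and 0.951% (0.769 to 1.16) and 0.246% (0.191 to 0.313) for Schwann-like cells. Cells without a class made up 25.0% of kept cells in normoxia and 59.8% in hypoxia. Among them were clusters that carried markers of unrelated classes, which held 4.45% (4.05 to 4.87) of kept cells in normoxia and 50.0% (49.5 to 50.6) in hypoxia. Most of these, 3.83% (3.46 to 4.23) and 44.5% (43.9 to 45.0) of kept cells, stayed without a class only by a rule set after the clusters were seen. With the clusters that this rule alone left unnamed given the class of their best markers, the ratio of shares, hypoxia over normoxia, was 2.12 in place of 0.472 for endothelium-like cells, 1.74 in place of 0.511 for fibroblast-like cells and 3.12 in place of 1.22 for macrophage-like cells. The ratio for glomus-like cells was 0.619, and it ranged from 0.175 with a mitochondrial limit of 10% to 0.955 at a clustering resolution of 0.5. With the order-of-magnitude UMI minimum the ratio was 0.726 for endothelium-like, 0.921 in fibroblast-like and 0.898 in glia-like cells against 0.367 as reported for the latter, and the smooth muscle-like ratio of 0.374 was 0.234 with the automatic Scrublet threshold. Dissociation, the UMI minimum and the lower depth in hypoxia can set such shares, so no direction in the tissue is drawn from them.

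**Figure D1:**
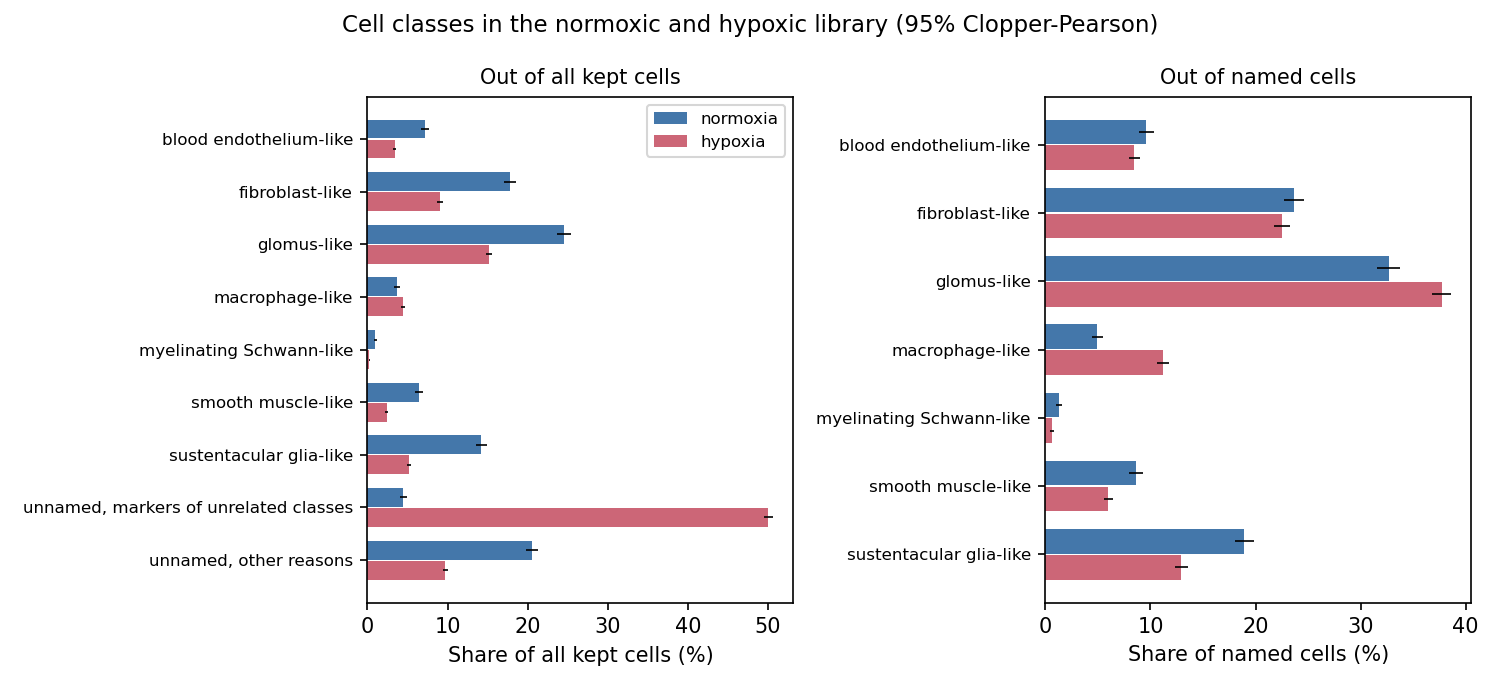
Share of cells per class in the normoxic and the hypoxic library, as a percentage of all kept cells and of the cells given a class, with exact 95% Clopper-Pearson intervals that cover counting error only. Glomus-like cells were 24.5% and 15.2% of kept cells but 32.7% and 37.7% of classed cells.

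In glomus-like cells, genes of glycolysis and of secretory granules were for the most part higher in hypoxia, as were Nnat, Pde10a, Slc18a1, Vegfa and Cox4i2. Nnat (ENSRNOG00000024923), which encodes the proteolipid neuronatin, stood at 175 (171 to 179.8) CPM in normoxia and 2458 (2442 to 2475) in hypoxia, a log2 of 3.81 (3.77 to 3.85). Pde10a, a cyclic nucleotide phosphodiesterase, had 79.3 (76.3 to 82.4) CPM in normoxia and 583 (575 to 591) in hypoxia, a log2 of 2.88 (2.82 to 2.94). Slc18a1, the vesicular monoamine transporter that loads catecholamines into granules, had 224 (219 to 229) CPM in normoxia and 955 (945 to 966) in hypoxia, a log2 of 2.09 (2.06 to 2.13). Vegfa, which encodes the vascular growth factor, had 144 CPM in normoxia and 376 in hypoxia and a log2 of 1.38 (1.33 to 1.43), and Cox4i2, an oxygen-dependent subunit of cytochrome oxidase that glomus cells need for oxygen sensing, had 1498 CPM in normoxia and 3972 in hypoxia and a log2 of 1.41 (1.39 to 1.42). Most glomus-like cells lay in clusters 9 (1470 of 2424 cells) and 14 (887) in normoxia and in clusters 1 (2613 of 4127) and 10 (1397) in hypoxia, so clusters and libraries nearly coincide, and a cluster mostly of 1 library may be that library, not a type. Nnat, Nrg3, Slc18a1, Scg2 and Chga are also among the genes that lead cluster 1, and Slc18a1, Th, Ddc, Chga, Chgb and Scg2 are markers used to name the class.

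The other genes with the largest higher values in glomus-like cells were Spats1 with a log2 of 3.44 (3.29 to 3.59), the neuregulin Nrg3 with 2.65 (2.58 to 2.72), Gpr155 with 2.58 (2.40 to 2.76) and the Rac activator Dock4 with 2.43 (2.30 to 2.56). Caly, a regulator of dopamine receptor trafficking, stood at 2.36 (2.30 to 2.42), the Wnt receptor Fzd5 at 1.77 (1.70 to 1.85) and Tmem130 at 1.74 (1.67 to 1.81). With a mitochondrial limit of 10%, which leaves a glomus-like share ratio of 0.175, the values were 6.69 for Spats1, 3.89 for Slc18a1, 4.14 for Fzd5, 3.68 for Gpr155, 2.02 for Vegfa and 2.17 for Cox4i2. Within cluster 14, an added alternative, Nnat was 1.31, Gpr155 0.63, Dock4 1.81, Caly 1.70, Spats1 4.67, Slc18a1 2.91 and Fzd5 2.79. Spats1 was 2.84 with a UMI minimum of 500 and 4.47 with cells thinned to 1000 UMIs.

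Among the lists fixed in advance, 15 of 19 measured genes of glycolysis were higher in hypoxic glomus-like cells, with a median log2 of 0.26, at percentile 99.7 among 10000 random lists matched on expression. Such percentiles describe these libraries and are no test of the conditions. Ldha, which turns pyruvate to lactate, had 602 CPM in normoxia and 1722 in hypoxia and a log2 of 1.52 (1.49 to 1.54). Within cluster 14 alone the glycolysis median was -0.0013, and Ldha was 0.91. Of the other targets of hypoxia-inducible factors, 12 of 19 were higher (median 0.093, percentile 91.6), among them the mitophagy receptor Bnip3 with 1.24 (1.19 to 1.30) and 0.39 within cluster 14, while Ndrg1 and the stress gene Ddit4 stood at -1.22 and -0.80. The glucose transporter Slc2a3, of the glycolysis list, stood at -0.84. Genes of secretory granules and exocytosis were higher in 14 of 19 cases (median 0.24, percentile 99.8), with the granins Chgb at 1.02, Scg2 at 1.01 and Chga at 0.80. With the mitochondrial limit of 10% Scg2 and Chga both stood at 2.28. The catecholamine list was split, with 7 of 13 higher and a median of 0.015 at percentile 67.6. In it Th, the rate-limiting enzyme of dopamine synthesis, had a log2 of 0.56 (0.54 to 0.58), which was 1.27 with the mitochondrial limit of 10%, its neighbour in the pathway Ddc 0.62 (0.60 to 0.63) and the cofactor enzyme Gch1 0.99 (0.92 to 1.06), or 0.35 within cluster 14. Cyb561 stood at -0.66. Lists tied to other cell types had larger medians in glomus-like cells than glycolysis or granules. Matrix genes were higher in 29 of 33 cases (0.99), inflammatory genes in 15 of 16 (1.01), angiogenesis genes in 17 of 20 (0.49) and contractile genes in 8 of 11 (0.33). After subtraction of the empty-droplet profile the matrix median was 0.20, and the angiogenesis median turned. Haemoglobin RNA in these cells stood at 40.2 CPM in normoxia and 512 in hypoxia.

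Of the acute oxygen sensing genes of glomus cells, 5 of 10 were higher, with a median of 0.088 at percentile 83.8. The median was 0.99 with the mitochondrial limit of 10% and -0.19 without cluster 14. Epas1, the oxygen-regulated transcription factor of these cells, stood at -0.042 (-0.070 to -0.013) and turned to 0.26 with that limit, the mitochondrial gene Higd1c stood at 0.51 (1.27 with that limit), and Ndufa4l2 at -0.46 (-0.47 to -0.45) with 6908 CPM in normoxia and 5029.8 in hypoxia. Adora2a, an adenosine receptor, had a log2 of 1.21, or 2.90 with that limit and 2.01 within cluster 14, and 8 of 15 measured receptors for transmitters and peptides were higher (median 0.30, percentile 96.8; -0.30 with thinned cells and -0.13 after subtraction of the empty-droplet profile). Nuclear-encoded oxidative phosphorylation genes, 19 of 34 of which were higher, had a median of 0.022 at percentile 74.9. Immediate early genes had a median of 0.079 at percentile 89.4, -0.63 with the mitochondrial limit of 10% and -0.65 within cluster 14. In that list the orphan nuclear receptor Nr4a1 stood at 1.93 (0.89 within cluster 14) and Ier3 at 2.10. Cholesterol synthesis genes were higher in 11 of 14 cases (median 0.23, percentile 99.6; -0.082 with the mitochondrial limit of 10%), and genes of the unfolded protein response were lower in 13 of 16 cases (median -0.25, percentile 1.05), among them Herpud1, which acts in clearing misfolded proteins, at -0.89 and the chaperone Calr at -0.58.

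Genes lower in hypoxic glomus-like cells included Fst, Cartpt, Id3 and Sox4. Fst (ENSRNOG00000011631), which encodes the activin antagonist follistatin, stood at 55.9 (53.4 to 58.5) CPM in normoxia and 3.81 (3.19 to 4.51) in hypoxia, a log2 of -3.88 (-4.14 to -3.62). Cartpt, a neuropeptide precursor, stood at 353 CPM in normoxia and 95.5 in hypoxia with a log2 of -1.88 (-1.94 to -1.83), but was -0.11 with the mitochondrial limit of 10%. The inhibitor of differentiation Id3 stood at -2.49 and at -1.06 without cluster 14, the histone gene H3f3c, uncertain for its near-identical copies, at -2.06 (-2.20 to -1.92), Sox4, a transcription factor of neuronal progenitors, at -2.20 (-2.29 to -2.12) and Ppp1r17 at -2.46. Fst was -3.14 with that mitochondrial limit, -1.78 with the mixed-profile clusters kept and -4.67 after subtraction of the empty-droplet profile.

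Other low values change with cluster 14, which held 36.6% (34.7 to 38.5) of glomus-like cells in normoxia and 1.96% (1.56 to 2.43) in hypoxia and which is led by Phox2a, Stmn2, Mest, Chrna7, Rbfox1, Grm7 and Prlh. It was picked as the glomus-like cluster with the most Stmn2, a ganglion neuron marker. It carried 8 of 12 glomus and 3 of 9 ganglion neuron markers, and cluster 1 also carried 3 of 9. Changes of neuronal genes and of its leading genes on its removal thus follow in part from this choice. Rbfox1, a neuronal splicing factor, had a log2 of -3.53 over all glomus-like cells and turned to 1.79 without this cluster. The prolactin-releasing peptide gene Prlh turned from -2.04 to 3.13 and Basp1 from -2.21 to 1.73. Dbh, which makes noradrenaline from dopamine, turned from -0.41 to 1.56, and the background potassium channel gene Kcnk3 from 0.22 to -0.19. The glutamate receptor Grm7 moved from -2.31 to -0.22, Tmem35a from -2.32 to -0.20, Sox4 to -1.18 and Ppp1r17 to -1.29. Rbfox1, Prlh, Basp1, Dbh and Kcnk3 also turned with a UMI minimum of 500, with no doublet removal, with the automatic Scrublet threshold and at resolution 0.5. At resolution 0.5 Rbfox1 was again 1.79, Basp1 1.73, Dbh 1.56 and Kcnk3 -0.19. That setting may thus leave out much the same cells and is no separate check. The cells of the class were regrouped under each of these settings, so none is independent of the split by cluster 14. Within cluster 14, Fst was -3.37, Cartpt -2.55, Sox4 -1.26, Dbh 0.27 and Prlh 0.37, whereas Rbfox1 and Basp1 did not turn and stayed lower in hypoxia.

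**Figure D2:**
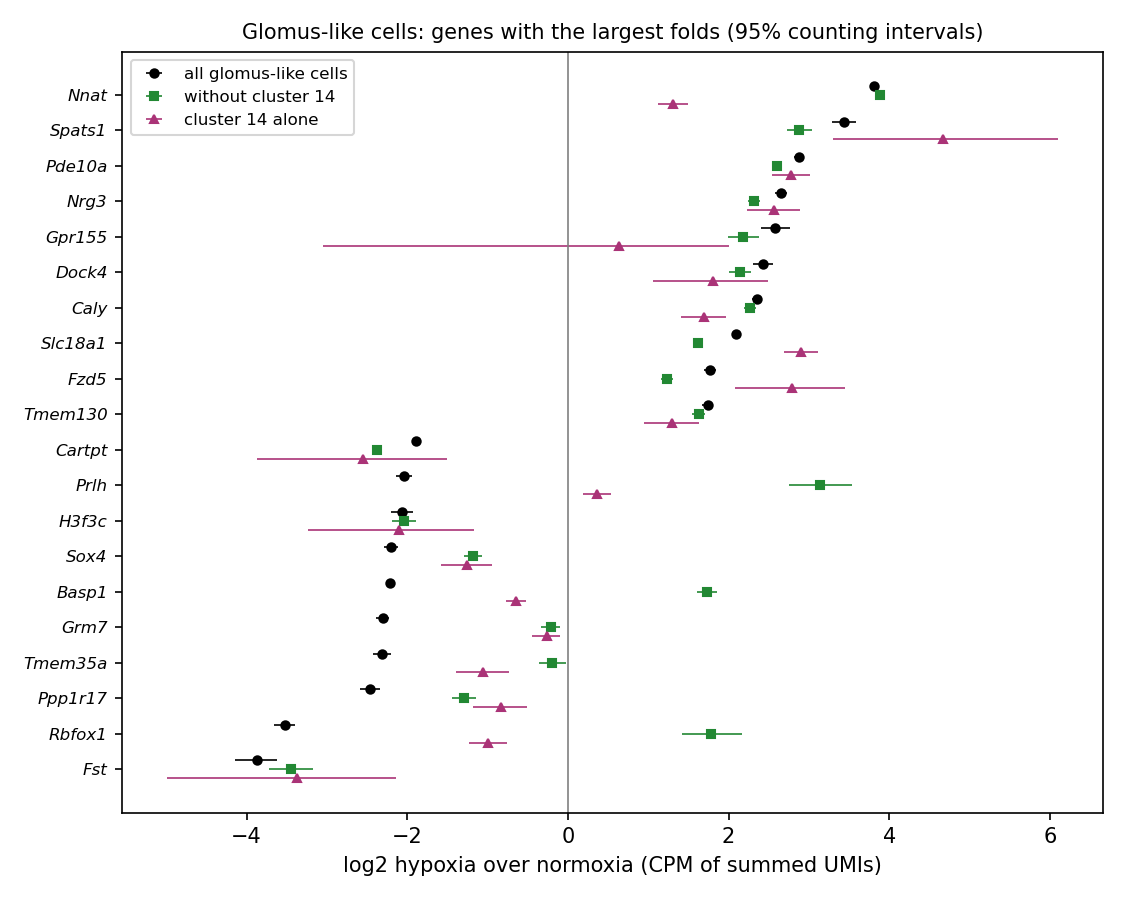
Log2 hypoxia over normoxia of the 20 genes with the largest values in glomus-like cells, over all such cells, without cluster 14 and in cluster 14 alone, with 95% intervals that cover counting error only. Rbfox1 stood at -3.53 over all cells and at 1.79 without cluster 14, whereas Fst stood at -3.88 and -3.44.

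In sustentacular glia-like cells, genes of cholesterol synthesis and of the extracellular matrix were for the most part higher in hypoxia, and Zbtb16 and Fkbp5 were among the genes with the largest lower values. Zbtb16 (ENSRNOG00000029980), a zinc finger transcription factor, stood at 116 (107 to 125) CPM in normoxia and 12.1 (9.22 to 15.7) in hypoxia, a log2 of -3.26 (-3.67 to -2.87). Fkbp5 (ENSRNOG00000022523), a co-chaperone of steroid receptors, stood at 117 (108 to 126) CPM in normoxia and 15.1 (11.8 to 19.0) in hypoxia, a log2 of -2.95 (-3.32 to -2.60). Mfap4, a microfibril protein, had 21.9 CPM in normoxia and 212 in hypoxia and a log2 of 3.28 (3.00 to 3.56), and the transcription factor gene Klf4 had 159 CPM in normoxia and 824 in hypoxia and a log2 of 2.37 (2.27 to 2.48). Cluster 5 held 1374 of 1402 glia-like cells in normoxia and 687 of 1416 in hypoxia, and cluster 15 held 28 and 729. Both carried 8 of 10 sustentacular glia markers. Cluster 5 also carried 5 of 9 myelinating Schwann markers, and cluster 15 had no glia marker among its 10 leading genes. Values of the class thus also follow its make-up, and those for cluster 5 alone are given beside the ones that differ most there. Within cluster 5, Zbtb16 was -3.26, Fkbp5 -2.94, Mfap4 2.58 and Klf4 1.69. Markers of other cell types were also higher in glia-like cells, with Chga at 1.57, Chgb at 1.26, Scg2 at 1.51, Th at 0.61 and the haemoglobin gene Hbb-b1 at 5.49, and within cluster 5 at 1.36, 1.14, 1.25, 0.75 and 3.64. After subtraction of the empty-droplet profile the medians were 0.82 for cholesterol synthesis and 0.36 for matrix. Scg2 was 7.19 and Hbb-b1 12.61 there, but subtracted sums under 3 UMIs were set to 3. Haemoglobin in normoxic glia-like cells stood at 2.85% of its empty-droplet level, under their free RNA share of 9.62%. Subtraction thus removed it in normoxia, so 12.61 is a bound, and the Scg2 value may be one too. In hypoxic glia-like cells subtraction did not remove either gene.

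Also lower in glia-like cells were the sulfotransferase Sult1a1 with -3.19 (-3.53 to -2.87), the transcription factor Klf15 with -2.68 (-3.04 to -2.34), the glutathione transferase Gsta1 with -2.64 (-2.83 to -2.46) and the glycerol-phosphate enzyme Gpd1 with -2.50. Sesn2 stood at -2.06, the lipase Pnpla7 at -2.03 and Gpt2, an alanine transaminase, at -1.82. Sult1a1 was -2.50 and Gpt2 -0.80 within cluster 5, and with the order-of-magnitude UMI minimum Gpd1 was -3.60 and Sesn2 -1.38. RT1-T24-1, at -3.11 and -3.79 within cluster 5, belongs to a family of near-identical histocompatibility genes, and its value is uncertain. Higher genes were Ltbp2, a matrix protein, with 3.01 (2.66 to 3.37) and 2.23 within cluster 5, the calcium-dependent factor Nfatc2 with 2.13 (1.57 within cluster 5), and the hyaluronan-binding Tnfaip6 with 2.09, which was 1.36 with thinned cells. The stress cytokine Gdf15 stood at 3.31 (2.72 with that UMI minimum), C1ql3 at 2.53 and the activin-binding Fstl3 at 2.02, and within cluster 5 they were 0.62, 1.12 and 0.71. The connective tissue growth factor Ccn2 turned from 2.09 to -0.43 within cluster 5 and the retinaldehyde dehydrogenase Aldh1a1 from 2.07 to -0.96.

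Of the cholesterol synthesis list, 13 of 14 measured genes were higher in glia-like cells, with a median of 0.80 at percentile 100. The enzymes Idi1 and Hmgcs1 had values of 1.99 and 1.26, and the regulator Insig1 had 1.28, and within cluster 5 they were 1.49, 0.85 and 0.77. Extracellular matrix genes were higher in 30 of 33 cases (median 0.46, percentile 100; 0.53 within cluster 5), with Ccn1 at 1.10, or 0.61 within cluster 5. Inflammatory genes were higher in 12 of 15 cases with a median of 0.87, which was -0.091 within cluster 5, where the chemokine gene Ccl2 turned from 1.5 to -1.32. Immediate early genes were higher in 13 of 19 cases (median 0.62, percentile 100), with Atf3 at 1.47. Glial genes were lower in 11 of 16 cases (median -0.19, percentile 3.06), among them the sodium-sensing channel gene Scn7a at -0.86, Apoe at -0.67 (-1.22 within cluster 5) and the neuregulin receptor Erbb3 at -0.62, which turned to 0.13 within cluster 5. Glycolysis genes were lower in 11 of 17 cases (median -0.16, percentile 20.7; -0.44 within cluster 5), with Aldoc at -1.59, and stem cell and neural crest genes were split, with 10 of 23 higher (median -0.074, percentile 35; 0.034 after subtraction of the empty-droplet profile and 0.03 with median ratio scaling). The astroglial filament gene Gfap stood at 0.0023 (-0.22 to 0.23), with 64.0 CPM in normoxia and 64.1 in hypoxia, with -0.43 in thinned cells and -0.62 within cluster 5. Sox10, a neural crest and glial transcription factor, stood at -0.32 (-0.43 to -0.22), or -0.16 within cluster 5, and the progenitor filament gene Nes at 0.42 (0.19 to 0.64), which turned to -0.39 within cluster 5. Gfap, Sox10 and Erbb3 also served to name glial clusters.

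Fibroblast-like cells had higher values of most matrix and cholesterol synthesis genes in hypoxia and lower values of most genes of the unfolded protein response. Cthrc1, a secreted protein of collagen-rich matrix, stood at 90.2 (85.0 to 95.7) CPM in normoxia and 484 (473 to 496) in hypoxia, a log2 of 2.42 (2.33 to 2.52). Igfbp3, an abundant carrier of insulin-like growth factors, stood at 9508 (9454 to 9563) CPM in normoxia and 2027 (2004 to 2051) in hypoxia, a log2 of -2.23 (-2.25 to -2.21), and the growth factor Igf2 had a log2 of -1.68 while Igf1 had 0.76. Further higher genes were Col11a1 with 2.36 (2.20 to 2.53), the collagen-binding integrin Itga1 with 1.98 (1.83 to 2.14), the chaperone Clu with 1.46 and the basement membrane collagen Col4a1 with 1.39 (1.34 to 1.44). Lower genes were Zbtb16 with -2.31 (-2.43 to -2.20), the vasopressin receptor Avpr1a with -2.31 (-2.52 to -2.10), Fkbp5 with -2.20 (-2.35 to -2.06) and the monooxygenase Fmo2 with -2.09 (-2.19 to -1.99). Extracellular matrix genes were higher in 30 of 34 cases (median 0.60, percentile 100), with Col6a3 at 1.26 and the matrix glycoprotein Thbs1 at 1.37, and cholesterol synthesis genes in 12 of 14 cases (median 0.63, percentile 100). Of the hypoxia-inducible factor targets other than glycolysis, 14 of 20 were lower (median -0.32, percentile 0.2), as were 13 of 15 genes of the unfolded protein response (median -0.37, percentile 0.05) and 15 of 17 antioxidant genes (median -0.29, percentile 0.98). With the mixed-profile clusters kept, Col11a1 was 1.73, Col6a3 0.67 and Igf2 -2.29, and the medians were 0.13 for matrix, -0.13 for antioxidant genes and 0.18 for the hypoxia-inducible factor targets. Itga1 was 1.23 with a UMI minimum of 2000 and 1.22 at resolution 0.5. The glucose transporter Slc2a1 stood at -0.79 and turned to 0.14 with the order-of-magnitude UMI minimum, 0.27 at resolution 2.0 and 0.057 with the mixed-profile clusters kept. The lists of glomus genes were higher in 6 of 9 cases for oxygen sensing (median 0.31) and 7 of 12 for catecholamines (0.27), and after subtraction of the empty-droplet profile the medians were 0.62 and -0.14, and 0.60 for matrix.

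In blood endothelium-like cells, which formed cluster 7 in both libraries, most genes of the matrix and of cholesterol synthesis were higher and most immediate early genes lower in hypoxia. Cluster 23, with 10 of 10 endothelial markers but without a class, is left out of these values (197 cells in normoxia and 135 in hypoxia). Ptn, which encodes the growth factor pleiotrophin, stood at 480.0 (462 to 499) CPM in normoxia and 2539 (2494 to 2583) in hypoxia, a log2 of 2.40 (2.34 to 2.46). The chemokine receptor Cxcr4 had 1.74 (1.38 to 2.10). The drug efflux pump Abcg2 stood at 152 (142 to 162) CPM in normoxia and 23.9 (19.8 to 28.6) in hypoxia, a log2 of -2.67 (-2.96 to -2.39), Tinagl1, a matrix-associated protein, at -2.54 (-2.71 to -2.38), Mal at -2.77 (-3.27 to -2.30) and the survival gene Bcl2l1 at -2.19 (-2.42 to -1.96). RT1-T24-1 stood at -3.39, or -3.99 with the mixed-profile clusters kept, and is uncertain because of its near-identical relatives. Of the matrix list, 25 of 31 genes were higher (median 0.58, percentile 100), with Col4a1 at 1.14, and of the cholesterol list 12 of 13 (median 0.49, percentile 99.9). Nid2, of the angiogenesis list, stood at 1.44. Immediate early genes were lower in 12 of 19 cases (median -0.42, percentile 0), among them the flow-responsive Klf2 at -0.69. The endothelin receptor Ednrb stood at 0.90 (0.82 to 0.99) and endothelin itself, Edn1, at 0.42 (0.23 to 0.61), and both turned with the mixed-profile clusters kept, to -0.31 and -0.54. With those clusters kept, Ptn was 1.49, Cxcr4 1.01, Abcg2 -3.69, Nid2 0.38, Col4a1 0.092 and Klf2 -1.58, and the medians were 1.79 for matrix and 1.64 for cholesterol synthesis. Cxcr4 was 2.36 with thinned cells. With no doublet removal Ptn was 1.49 and Edn1 -1.0. Of the secretory granule list, 12 of 17 genes were higher (median 0.23, 0.13 after subtraction of the empty-droplet profile, where the matrix median was 0.50).

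Smooth muscle-like cells lay mainly in cluster 13 (599 of 637 cells in normoxia and 506 of 655 in hypoxia), with the rest in cluster 25 (38 and 149). These cells were not analysed by cluster, so their values also follow this mix. Their contractile genes were split, with 6 of 12 higher and a median of 0.022 at percentile 59.9 (-0.31 with the order-of-magnitude UMI minimum), among them the filament gene Des at -0.84, the actin gene Acta2 at -0.54 and the myosin light chain gene Myl9 at 0.39. The metallothionein gene Mt1, which binds zinc and copper, had -2.24 (-2.84 to -1.69), Rasl11b -1.44 (-1.78 to -1.11), Ehd1 -1.40 and the kinase Eef2k -1.38. Higher values were found for the orphan receptor Gpr176 with 2.18 (1.80 to 2.57) and for Thbs1 with 1.57, and matrix genes were higher in 25 of 33 cases (median 0.52, percentile 100; 0.083 at resolution 0.5). Lists of glomus genes were higher as well, in 13 of 17 cases for secretory granules (median 0.82, percentile 100) and 8 of 9 for catecholamines (median 0.66, percentile 100), and the estimated share of free RNA was 6.51% in normoxia and 9.11% in hypoxia. After subtraction of the empty-droplet profile the medians were 0.10 for secretory granules and 0.48 for matrix, while Scg2 stood at 3.92 in place of 1.81. Immediate early genes were lower in 14 of 19 cases (median -0.46, percentile 0). The adhesion receptor Adgrf5 stood at 2.48 (2.05 to 2.92) but at 0.053 at resolution 0.5, where Chrdl1 was 0.73 in place of 1.98, Ntm 0.37 in place of 1.84 and Col6a2 0.57 in place of 1.64, and where Sytl2 turned from 1.74 to -0.081, Tnc from 1.60 to -0.95 and Col6a1 from 1.56 to -0.13. Sytl2 and Tnc also turned with no doublet removal (-0.032 and -0.57) and with the automatic Scrublet threshold, where Ntm was 0.34, Adgrf5 0.67, Chrdl1 1.29, Col6a1 0.50 and Col6a2 0.87. Gpr176 was 2.89 with the order-of-magnitude UMI minimum and 3.03 with the automatic Scrublet threshold.

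Macrophage-like cells, 365 in normoxia and 1222 in hypoxia, had lower values of Ciita and of class II histocompatibility genes in hypoxia, and higher Trem2 and Apoe. Cluster 21, led by class II genes and with 3 of the 6 dendritic cell markers, held 38.4% (33.3 to 43.6) of the class in normoxia and 18.0% (15.9 to 20.3) in hypoxia, and cluster 12 held 60.8% (55.6 to 65.9) and 78.0% (75.6 to 80.3), so values of the class also follow its make-up. Genes of other cell types were higher too, with 6 of 6 oxygen sensing genes of glomus cells (median 1.22), 15 of 17 of secretory granules (1.0), 8 of 8 contractile (0.46) and 25 of 31 matrix genes (0.92), and the estimated share of free RNA was 4.35% in normoxia and 6.89% in hypoxia. After subtraction of the empty-droplet profile the medians turned to -0.50 for secretory granules and -0.37 for matrix, while Ciita was -1.44, Trem2 1.76 and Apoe 0.96. The fixed markers of other classes, which set the subtracted share, include members of both lists, such as Scg2, Chga and Col1a1. These 2 turned medians thus depend in part on the method. Ciita, the master regulator of class II histocompatibility genes, stood at 169.7 (156 to 184) CPM in normoxia and 61.3 (55.5 to 67.6) in hypoxia, a log2 of -1.47 (-1.65 to -1.28), and the invariant chain gene Cd74 at -0.83, RT1-Ba at -0.76 and RT1-Da at -0.76. Within cluster 12 alone these were -1.19, -0.68, -0.55 and -0.58, and within cluster 21 -0.64, -0.31, -0.16 and -0.18. Trem2, a lipid-sensing receptor, stood at 87.4 (77.6 to 98.0) CPM in normoxia and 289 (276 to 302) in hypoxia, a log2 of 1.72 (1.54 to 1.91), and Apoe at 0.91, and within cluster 12 they were 1.18 and 0.34, while cluster 21 held 5 and 4 UMIs of Trem2. The ficolin Fcna had 1.67 (1.47 to 1.88) and Mamdc2 2.51 (2.02 to 3.05), and within cluster 21 these were 1.03 and 1.44. Fkbp5 stood at -1.98 (-2.17 to -1.78), the chemokine receptor Ccr6 at -1.65 (-2.00 to -1.30) and the lymphocyte-homing integrin Itgb7 at -1.57, and within cluster 21 they were -1.82, -0.60 and -0.62, while cluster 12 held 0 and 9 UMIs of Itgb7. The largest lower value was that of RT1-CE1, -4.83 (-5.44 to -4.28), which is uncertain because reads of near-identical RT1 genes and alleles can be split between them, and it lay between -5.42 and -3.75 under other settings. Chp2 stood at 1.87 and the potassium channel Kcnk10 at 1.78, or 1.18 within cluster 12, and Chp2 was 0.92 within cluster 21. Of the interferon and antigen presentation list 12 of 20 genes were lower (median -0.19, percentile 0.62; -0.29 within cluster 12, 0.0079 within cluster 21 and -0.39 with the mixed-profile clusters kept), and of the unfolded protein response list 13 of 14 (median -0.48, percentile 0.01). Trem2 was 1.02 and Ccr6 -2.36 with thinned cells, Mamdc2 1.75 with no doublet removal, and Ciita -2.12, RT1-Ba -1.35, Chp2 1.27 and Kcnk10 1.0 with the mixed-profile clusters kept.

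Myelinating Schwann-like cells, 94 in normoxia and 67 in hypoxia, gave wide intervals. Klf4 had a log2 of 1.87 (1.27 to 2.48) and the isoprenoid enzyme Idi1 1.35 (0.95 to 1.75), with 8 of 10 cholesterol synthesis genes higher (median 0.67, percentile 100). Genes of other cell types were higher as well, with Scg2 at 2.14, Col3a1 at 2.54, Hbb-b1 at 3.29 and 5 of 5 oxygen sensing genes of glomus cells (median 1.16), and the estimated share of free RNA was 7.52% in normoxia and 15.5% in hypoxia. After subtraction of the empty-droplet profile Col3a1 was 3.60, Klf4 2.16, Idi1 1.46 and the cholesterol synthesis median 0.76. Glial genes were lower in 8 of 12 cases (median -0.38, percentile 0.23). The Notch effector Hes1 stood at 1.84 (1.02 to 2.69) and Atf3 at 1.78 (1.23 to 2.34), which were 1.0 and 0.68 with no doublet removal. Tmem140 stood at -2.71 and the caveolar gene Cav1 at -2.16, which were -1.53 and -0.89 under that setting, and Cav1 was -3.14 with the mitochondrial limit of 10%.

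**Figure D3:**
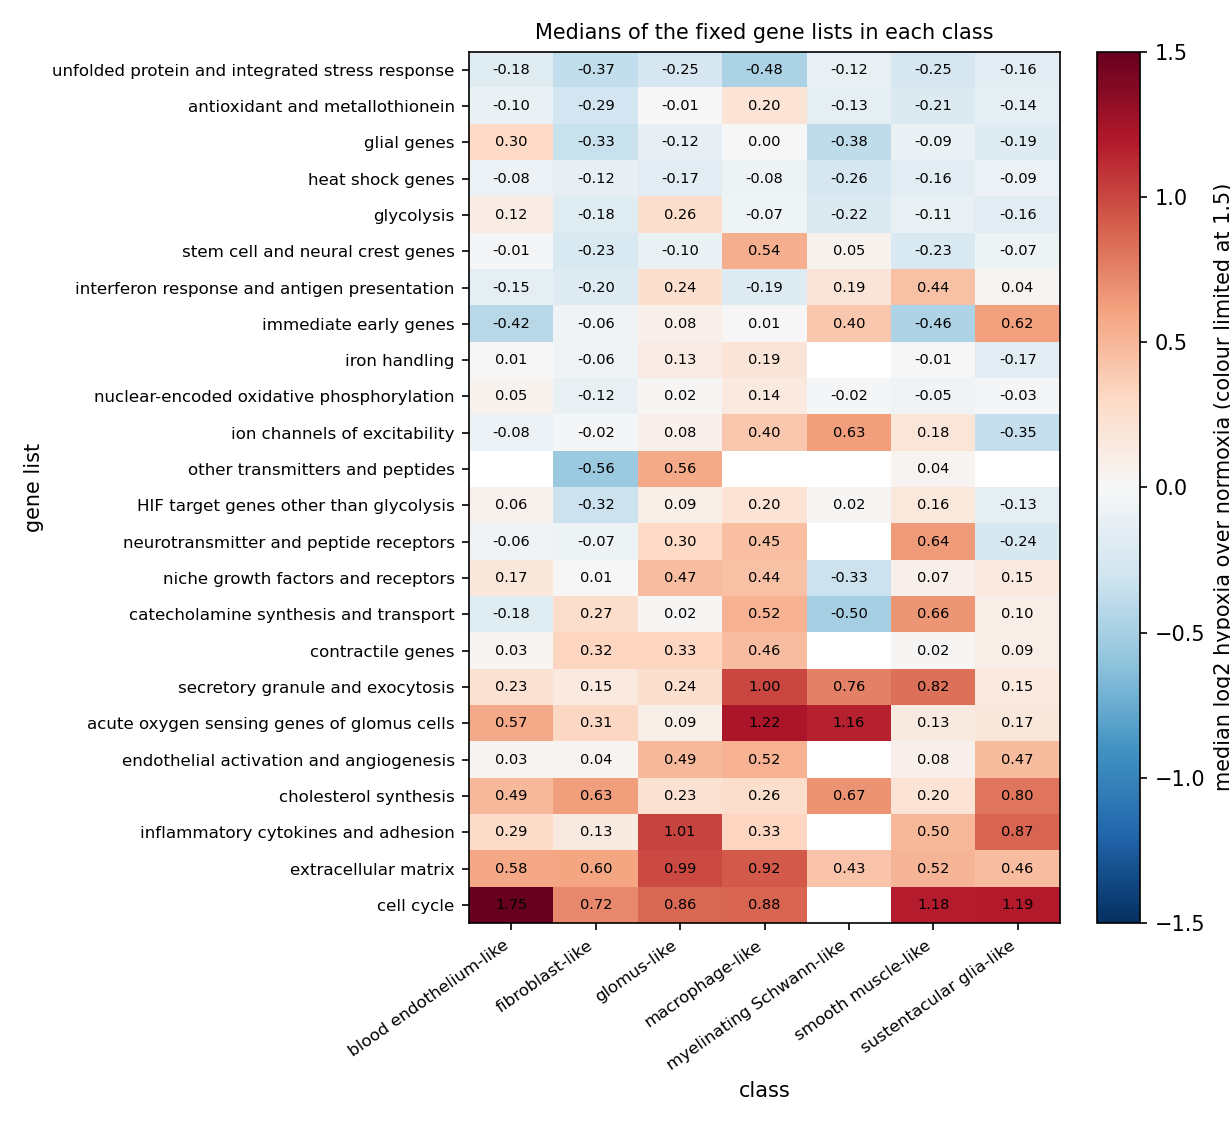
Median log2 hypoxia over normoxia of each gene list in each of the 7 classes, with colour limited at 1.5 and blanks where under 5 members were measured. Cholesterol synthesis stood at 0.80 in glia-like, 0.63 in fibroblast-like and 0.23 in glomus-like cells, and the matrix median of 0.99 in glomus-like cells was 0.20 after subtraction of the empty-droplet profile.

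Because the series is about the stem cell niche, cells with a UMI of any of 8 cell-cycle genes were counted after each cell was thinned to 1000 UMIs, which left out no kept cell. Such cells made up 1.03% (0.842 to 1.25) of kept cells in normoxia and 8.19% (7.87 to 8.52) in hypoxia, and 6.33% and 17.2% without thinning. Draws of 1000 UMIs from empty droplets carried such a UMI in 1.61% of cases in normoxia and 14.2% in hypoxia, and the estimated share of free RNA in a class sets how much of this its cells would carry. In glia-like cells (median depths 3539 and 3032 UMIs) the thinned share was 0.856% (0.443 to 1.49) in normoxia and 2.90% (2.09 to 3.91) in hypoxia, and free RNA alone would give 0.156% and 1.58%. Glomus-like cells (13792 and 8062) had 1.16% (0.769 to 1.67) and 1.55% (1.2 to 1.98) against 0.0476% and 0.626% from free RNA, and macrophage-like cells (8551 and 5157) 2.74% (1.32 to 4.98) and 4.42% (3.34 to 5.73) against 0.0707% and 1.05%. Endothelium-like cells had 1.69% (0.874 to 2.93) and 3.46% (2.38 to 4.85) against 0.0743% and 1.01%. In hypoxic fibroblast-like and smooth muscle-like cells the shares of 1.26% (0.856 to 1.78) and 2.14% (1.17 to 3.56) included the 0.925% and 1.38% from free RNA within their intervals. The class shares leave out cluster 16, which is led by cell-cycle genes such as Top2a and Mki67 and has no class. It held 12 cells in normoxia and 706 in hypoxia, so the classes do not show all cells with such transcripts. The estimates of free RNA carry no interval, and no cycling is read from single UMIs. Within the lists, 15 of 16 cell-cycle genes were higher in glia-like (median 1.19), 17 of 20 in glomus-like (0.86) and 18 of 19 in endothelium-like cells (1.75). So were 22 of 23 in macrophage-like (0.88), 8 of 9 in smooth muscle-like (1.18) and 14 of 19 in fibroblast-like cells (0.72). With thinned cells the medians were 0.11 in glia-like, -0.050 in glomus-like and 0.26 in endothelium-like cells. The minimum of 20 UMIs was applied anew to the thinned sums, so these medians can rest on other, more abundant members. They do not show that depth made the rise.

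Ligands and receptors of the niche were read within each library, and Edn1 and its receptor gene Ednrb were both found in endothelium-like cells. Levels in empty droplets are not set beside the levels given here, so free RNA may contribute to them. Edn1 had 76.9 (69.8 to 84.5) and 103 (94.2 to 112) CPM in normoxic and hypoxic endothelium-like cells, where Ednrb had 297 (282 to 311) and 555 (535 to 576), and in glia-like cells Ednrb had 79.5 (72.3 to 87.2) and 104 (94.9 to 113). The kit ligand gene Kitlg had 664 (643 to 686) and 841 (815 to 866) CPM in endothelium-like cells. Gdnf, a neurotrophic factor, had 18.2 (16.8 to 19.7) and 32.1 (30.3 to 34.1) CPM in glomus-like cells, and Nrg1, a ligand of the glial receptor Erbb3, had 18.1 (16.7 to 19.6) and 32.4 (30.6 to 34.4). Igf1 had 436 (425 to 448) and 739.8 (726 to 754) CPM in fibroblast-like cells and 255 (238 to 273) and 435 (419 to 451) in macrophage-like cells. Of the niche growth factors and receptors, 13 of 24 were higher in glia-like cells (median 0.15, percentile 99.6; -0.15 after subtraction) and 19 of 28 in glomus-like cells (median 0.47, or 1.04 with the mitochondrial limit of 10%).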

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

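The tests of free RNA and of the cells themselves for haemoglobin and both tests on mixed-profile barcodes were chosen only after the result was seen, while the test of red-cell droplets was written before.

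A signal outside the compared classes was found in the barcodes of clusters with markers of unrelated classes, which held 50.0% of kept barcodes in hypoxia (13621) and 4.45% in normoxia (440). Their median depth in hypoxia was 1783 UMIs, which is 0.301 of the 5918.5 of the cells with a class. Droplets that hold more than 1 cell should be deeper than the cells with a class. The low median thus argues against them for most of these barcodes but cannot exclude them for a part. Cluster 0, with 6098 hypoxic barcodes at a median of 1396 UMIs, weighs most in it. Clusters 19, 26 and 31 had medians of 13058, 10859 and 12015 UMIs, and 12828 barcodes had been removed as doublets before. In normoxia the mixed-profile barcodes had a median of 19252 UMIs against 6994 for all kept cells. The shares of 50.0% and 4.45% may thus compare unlike barcodes. Across 11643 genes, which are not independent replicates, the profile of the hypoxic mixed-profile barcodes correlated with that of the empty droplets of the same library at r of 0.974, above each class (at most 0.822). Droplets of free RNA are a candidate explanation, but the pooled cells with a class reached 0.966, so the correlation separates weakly, and no biological explanation was tested.

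Haemoglobin RNA in empty droplets, a measurement outside the comparisons, stood at 22232 CPM (22095 to 22370) in hypoxia and 6067 CPM (5977 to 6159) in normoxia. In the hypoxic library, haemoglobin exceeded 3 times the level that the free RNA share allows in 5 of the 7 classes, which argues against evenly spread free RNA as the whole source. In fibroblast-like cells the 5% of cells with the most haemoglobin held 97.6% of its UMIs, which argues against expression by the fibroblast-like cells in general and is consistent with a few droplets that caught a red cell. In glomus-like cells that share was 51.2% and in Schwann-like cells 22.1%, where haemoglobin stayed within the free RNA level. Cluster 31, with 51 hypoxic barcodes, was led by haemoglobin genes, carried 10 of 12 glomus markers and stayed without a class. The glomus-like values may thus be low in part because such barcodes were left out.

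Cell-cycle transcripts were also found in empty droplets, which lie outside the compared classes, and draws of 1000 UMIs from empty droplets held a cell-cycle UMI in 14.2% of cases in hypoxia and 1.61% in normoxia. Cluster 16, led by Ube2c, Top2a, Cenpf and Mki67, held 12 cells in normoxia and 706 in hypoxia with markers of several classes, and stayed without a class. Its hypoxic cells had a median of 4119 UMIs. Their profile correlated with that of empty droplets at r of 0.915, below the 0.974 of all mixed-profile barcodes but above each class (at most 0.822).

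Fst stood lower in hypoxic glomus-like cells, with a log2 of -3.88, and higher in hypoxic glia-like cells, with 1.99. The opposite directions drew attention to it under a rule set after the data were seen, and the difference was not tested. The glia-like value is over clusters 5 and 15 together, of which cluster 15 held 28 cells in normoxia and 729 in hypoxia. Fst was not computed within cluster 5 alone, so its value there is open.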

How the results depend on the processing

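Of the alternatives here, keeping the mixed-profile clusters and the splits by clusters 14, 5, 12 and 21 were chosen only after the data were seen. Among 702 log2 values of genes, alternatives moved the value 2419 times beyond its counting interval, turned it 215 times and left it within the interval 8868 times. For 158 list medians these numbers were 101, 7 and 2750, and for 37 shares and share ratios 117, 2 and 104. A value is counted as turned only where its own interval excluded 0, or 1 for a ratio, and the sign also differed for 23 of the list medians counted as moved and 228 of those within the interval, and for 90 and 137 such values of genes. Adding 1 UMI moved 0 and turned 0 values, and scaling within each library moved 25, totals without mitochondrial and ribosomal genes 7 and no thinning 14, with 0 turned under each of these. Median ratio scaling shifts the median of all genes by 0.125 in fibroblast-like and 0.106 in glia-like cells, as their all-gene medians were -0.12 and -0.11, and among genes it turned only Fth1 in fibroblast-like cells. Across every alternative run, Nnat in glomus-like cells stayed at 1.31 or higher and Fst there at -1.78 or lower, Zbtb16 and Fkbp5 in glia-like cells stayed lower in hypoxia, and the cholesterol synthesis median in glia-like cells stayed at 0.54 or higher. No paired analysis was possible because each group holds replicate 1 alone. Values below are log2 values, list medians under short names of the lists, or ratios of shares, hypoxia over normoxia. Splits by cluster use fewer cells by construction, and for all other values that turned or moved the cause was not tested. Depth limits Schwann-like cells, with 94 and 67 cells, the most.

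With a UMI minimum of 500, 114 values moved and 10 turned. In glomus-like cells Basp1 was 1.80, Dbh 1.59, Igf1r 0.15, Kcnk3 -0.22, Pgf -0.25, Prlh 2.11, Rbfox1 2.06 and Sparcl1 -0.23. In smooth muscle-like cells Ndufa4l2 was -0.068. In Schwann-like cells Tagln was 0.87. Macrophage-like list median was 1.13 for contraction. The share ratio was 0.423 for fibroblast-like and 0.933 for glomus-like cells. With a minimum of 2000, 98 moved and 2 turned. In endothelium-like cells Stmn1 was 0.014. Among smooth muscle-like cells Syt1 was -0.22. The ratio of shares was 0.652 for endothelium-like, 0.634 for fibroblast-like, 0.798 for glomus-like, 1.58 for macrophage-like, 0.492 for smooth muscle-like and 0.397 for glia-like cells. The order-of-magnitude minimum moved 221 and turned 15. In glia-like cells Ndufa4l2 was -0.16, Npy -0.17 and Stmn1 0.020. In fibroblast-like cells Fth1 was 0.0087 and Slc2a1 0.14. In endothelium-like cells Myl9 was 0.051 and Th -0.39. Across smooth muscle-like cells Cxcl1 was 0.41, Ece1 0.054, Gpi 0.036, Nfkbia 0.085, Rgs4 -0.10, Scn7a 0.31, Syt1 -0.67 and Tnc -0.083. The glia-like medians were -0.33 for glycolysis and 0.76 for interferon. List medians in endothelium-like cells were -0.17 for secretion, 0.94 for matrix and 0.72 for contraction. Smooth muscle-like list median was 0.46 for glia. The macrophage-like medians were 1.61 for secretion, 0.20 for oxidative phosphorylation and 0.74 for stem genes. Share ratios came to 0.726 for endothelium-like, 0.921 for fibroblast-like, 0.830 for glomus-like, 1.69 for macrophage-like, 0.274 for smooth muscle-like and 0.898 for glia-like cells. A mitochondrial limit of 10% moved 185 and turned 11. In glomus-like cells Cdh19 was 0.035, Egr1 -0.34, Epas1 0.26, Gabbr1 -0.14, Ier2 -0.97, Ngfr 0.34 and Slc2a1 -0.032. In glia-like cells Nrp2 was 0.00048. In endothelium-like cells Gfap was -0.049. In Schwann-like cells Cald1 was -0.024 and Ccn2 -1.09. List medians in glomus-like cells were 0.99 for oxygen sensing, 1.05 for glia, 1.04 for niche factors, 0.71 for contraction, 0.70 for inflammation, 0.90 for interferon, -0.63 for immediate early genes and -0.082 for cholesterol synthesis. Macrophage-like list medians were 1.38 for cell cycle and 0.11 for contraction. Shares had ratios of 0.175 for glomus-like and 0.410 for glia-like cells.

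Without doublet removal 219 moved and 21 turned. In glomus-like cells Basp1 was 1.70, Cacna1d -0.0028, Dbh 1.60, Igf1r 0.13, Kcnk3 -0.19, Pgf -0.24, Prlh 2.94, Rbfox1 2.10 and Sparcl1 -0.22. In endothelium-like cells Edn1 was -1.0 and Vegfa -0.14. In smooth muscle-like cells Nfkbia was 0.0062, Syt1 -0.59, Sytl2 -0.032 and Tnc -0.57. In macrophage-like cells Bhlhe40 was 0.26, Ftl1 -0.080, Kitlg -0.041 and Pgam1 0.092. In Schwann-like cells Id1 was -0.19 and Tagln 0.95. The macrophage-like medians were 0.21 for oxidative phosphorylation, 0.83 for glia, 0.99 for niche factors, 1.5 for matrix and 0.57 for cholesterol synthesis. List median in Schwann-like cells was 0.097 for oxygen sensing. As a ratio, shares were 0.363 for endothelium-like, 0.433 for fibroblast-like, 0.734 for glomus-like, 1.54 for macrophage-like, 0.254 for smooth muscle-like and 0.289 for glia-like cells. The automatic Scrublet threshold moved 216 and turned 16. In glomus-like cells Basp1 was 1.91, Cacna1d -0.0021, Dbh 1.61, Igf1r 0.14, Kcnk3 -0.20, Pgf -0.25, Prlh 3.06, Rbfox1 1.79 and Sparcl1 -0.23. Among smooth muscle-like cells Gpi was 0.038, Nfkbia 0.13, Scn7a 0.92, Syt1 -0.23, Sytl2 -0.053 and Tnc -0.13. In Schwann-like cells Tagln was 1.93. Smooth muscle-like list median was 1.0 for glia. The macrophage-like medians were 1.40 for cell cycle, 1.48 for stem genes, 1.07 for glia, 1.11 for niche factors, 1.67 for angiogenesis, 2.48 for matrix and 2.02 for contraction. List medians in Schwann-like cells were 1.96 for oxygen sensing, 1.03 for niche factors and 0.74 for matrix. The share ratio was 0.384 for endothelium-like, 0.411 for fibroblast-like, 0.693 for glomus-like, 1.04 for macrophage-like, 0.234 for smooth muscle-like and 0.270 for glia-like cells.

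At resolution 0.5, 176 moved and 14 turned. In glomus-like cells Basp1 was 1.73, Dbh 1.56, Igf1r 0.13, Kcnk3 -0.19, Pgf -0.24, Prlh 3.14, Rbfox1 1.79 and Sparcl1 -0.21. Across smooth muscle-like cells Col6a1 was -0.13, Cox4i2 0.00022, Cxcl12 -0.24, Nfkbia 0.10, Sytl2 -0.081 and Tnc -0.95. Smooth muscle-like list median was 0.083 for matrix. The ratio of shares was 0.955 for glomus-like and 0.303 for smooth muscle-like cells. At resolution 2.0, 127 moved and 9 turned. In glia-like cells Ndufa4l2 was -0.011 and Nrp2 0.66. In fibroblast-like cells Fth1 was 0.071 and Slc2a1 0.27. In smooth muscle-like cells Cxcl12 was -0.51, Kcnk3 0.40, Ncam1 -0.22, Ndufa4l2 -0.071 and P4ha1 -0.027. Share ratios came to 0.616 for fibroblast-like, 0.297 for smooth muscle-like and 0.507 for glia-like cells.

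Keeping the mixed-profile clusters moved 296 and turned 35. In glomus-like cells Ier2 was -0.16. In fibroblast-like cells Ednra was -0.055, Eno2 0.38, Nrp1 -0.31, Pcsk1n 0.99, Pgam1 0.37, Scn7a 1.47, Slc2a1 0.057, Tpi1 0.49, Vamp2 0.20 and Vegfa 0.18. In endothelium-like cells Atp5f1b was 0.075, Cebpd 0.33, Col4a2 -0.12, Edn1 -0.54, Ednrb -0.31, Ftl1 0.38, Gch1 0.70, Hspd1 0.15, Icam1 -0.16, Myl9 1.26, Sod2 0.56, Sparc -0.20, Stmn1 1.48, Tnfaip3 -0.0075, Tpi1 1.09 and Tpm1 0.51. In macrophage-like cells Bhlhe40 was 0.54, Dbh 0.019, Ftl1 -0.25, Kitlg -0.044, Pgam1 0.26 and Slc2a1 -0.13. The glomus-like medians were 0.46 for matrix and -0.16 for immediate early genes. List medians in fibroblast-like cells were 0.37 for glycolysis, 0.18 for other HIF targets, 2.75 for oxygen sensing, 1.62 for catecholamines, 2.60 for secretion, 0.23 for oxidative phosphorylation, 2.91 for cell cycle, 0.74 for stem genes, 1.48 for glia, 1.18 for angiogenesis, 0.13 for matrix and -0.13 for antioxidants. Endothelium-like list medians were 0.60 for glycolysis, 3.58 for oxygen sensing, 1.19 for catecholamines, 3.47 for secretion, 2.80 for ion channels, 2.26 for receptors, 0.37 for oxidative phosphorylation, 3.15 for cell cycle, 1.78 for stem genes, 2.36 for glia, 1.78 for niche factors, -1.03 for angiogenesis, 1.79 for matrix, 2.68 for contraction, -0.65 for interferon and 1.64 for cholesterol synthesis. The macrophage-like medians were 3.93 for oxygen sensing, 3.55 for secretion, 1.88 for ion channels, 0.47 for oxidative phosphorylation, 2.68 for stem genes, 2.02 for glia, 2.03 for niche factors, 2.33 for angiogenesis, 3.24 for matrix, 2.70 for contraction, -0.39 for interferon, -0.28 for unfolded protein, 0.45 for antioxidants and 1.10 for cholesterol synthesis. Shares had ratios of 2.12 for endothelium-like, 1.74 for fibroblast-like and 3.12 for macrophage-like cells.

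Median ratio scaling moved 95 and turned 1. In fibroblast-like cells Fth1 was 0.067. List median in glia-like cells was 0.081 for oxidative phosphorylation. Fibroblast-like list median was 0.0079 for oxidative phosphorylation. The mean over cells of each cell's share moved 135 and turned 2. In glia-like cells Nrp2 was 0.013. In macrophage-like cells Epas1 was -0.13. The macrophage-like medians were 1.2 for cell cycle and 0.023 for cholesterol synthesis. Thinned cells moved 302 and turned 15. In glomus-like cells Top2a was -0.031. In glia-like cells Nrp2 was 0.021. In fibroblast-like cells Ednrb was -0.43, Epas1 -0.073, Fth1 0.0042 and Th -0.035. In endothelium-like cells Gpx4 was -0.0052. Among smooth muscle-like cells Fgfr1 was 0.17 and Pdia6 0.32. In macrophage-like cells Ednrb was -0.52, Epas1 -0.36 and Id2 0.066. In Schwann-like cells Fdft1 was -0.40. List medians in glomus-like cells were -0.050 for cell cycle and 0.76 for matrix. Glia-like list median was 0.11 for cell cycle. The endothelium-like median was 0.26 for cell cycle. List median in macrophage-like cells was -0.033 for niche factors. Schwann-like list median was -0.096 for matrix. Subtraction of the empty-droplet profile moved 79 and turned 15. In glomus-like cells Sparc was -0.088. In glia-like cells Cox4i2 was -0.12 and Vegfa -0.13. In fibroblast-like cells Cox4i2 was -2.80 and Scn7a 0.039. In endothelium-like cells Rgs5 was -1.96, Th -3.43 and Vegfa -1.78. Across smooth muscle-like cells Ldha was -0.068. In macrophage-like cells Col1a2 was -3.87, Epas1 -0.056 and Sparc -0.054. The glomus-like medians were -0.044 for angiogenesis and 0.20 for matrix. List medians in macrophage-like cells were -0.50 for secretion and -0.37 for matrix. List members with at least 100 UMIs moved 1 median. Endothelium-like list median was 0.41 for cell cycle. No minimum for list members moved 1. The Schwann-like median was 1.26 for niche factors.

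Glomus-like cells without cluster 14 moved 68 and turned 8. In glomus-like cells Basp1 was 1.73, Dbh 1.56, Igf1r 0.13, Kcnk3 -0.19, Pgf -0.24, Prlh 3.13, Rbfox1 1.79 and Sparcl1 -0.22. Cluster 14 alone moved 88 and turned 11. In glomus-like cells Cacna1d was -0.025, Dbh 0.27, Drd2 0.058, Egr1 -0.16, Eno2 -0.032, Epas1 0.047, Gpx4 0.036, Ier2 -1.31, Prlh 0.37 and Slc2a1 -0.95. List medians in glomus-like cells were -0.0013 for glycolysis and -0.65 for immediate early genes. Glia-like cells of cluster 5 alone moved 68 and turned 19. In glia-like cells Aldh1a1 was -0.96, Bhlhe40 -0.030, Ccl2 -1.32, Ccn2 -0.43, Cox4i2 -0.067, Eln -1.39, Erbb3 0.13, Fbln2 -1.06, Id2 0.20, Ldha -0.084, Myl9 -0.0022, Ndufa4l2 -0.31, Nes -0.39, Npy -2.41, Nrp2 0.94, Sod2 -0.11, Stmn1 0.35 and Tgfb2 -2.07. Glia-like list medians were -0.091 for inflammation and -0.44 for glycolysis. Macrophage-like cells of cluster 12 alone moved 44 and turned 7. In macrophage-like cells Bhlhe40 was 1.92, Ednrb -0.15, Ftl1 -0.17, Id2 0.083, Itgb7 0.011, Slc2a1 -0.098 and Sparc -0.040. The Itgb7 value is a bound, with 0 UMIs in normoxia and 9 in hypoxia. Those of cluster 21 alone moved 58 and turned 13. In macrophage-like cells Bhlhe40 was 0.35, Ccl3 1.18, Ccl4 0.81, Col1a2 -0.23, Egr2 0.86, Fth1 -0.0055, Ftl1 -0.29, Id2 0.21, P2ry12 -0.16, Sod2 -0.21, Tnf 0.18, Trem2 -0.14 and Vim -0.13. The macrophage-like medians were 0.079 for oxidative phosphorylation, 1.09 for cell cycle, 0.42 for matrix, 0.67 for inflammation, 0.019 for antioxidants and 0.60 for cholesterol synthesis.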

Other observations

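The tests of glucocorticoid signalling were chosen only after the result was seen, as were the genes set side by side across classes here, while those of depth, free RNA and time of day were written before.

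Of the heat shock list, 8 of 10 measured genes were lower in hypoxia in glomus-like cells, 7 of 10 each in fibroblast-like, endothelium-like and smooth muscle-like cells, 6 of 10 each in glia-like and macrophage-like cells and 6 of 9 in Schwann-like cells, with medians between -0.26 and -0.078 at percentiles from 4.95 to 20.4. Against this, Hsph1, a co-chaperone of the heat shock protein 70 family, was higher in hypoxia in 6 classes, with log2 values of 1.26 in macrophage-like, 1.16 in endothelium-like, 1.03 in fibroblast-like, 0.66 in glia-like, 0.54 in glomus-like and 0.51 in smooth muscle-like cells. The value in Schwann-like cells rested on 21 UMIs in normoxia and 5 in hypoxia and was -0.81 (-2.58 to 0.63). Hspa8, the constitutive member of that family, was lower in all 7, from -0.68 in endothelium-like to -0.27 in Schwann-like cells, with -0.51 in glomus-like cells. Herpud1, a target of the unfolded protein response, stood at -0.90 in endothelium-like, -0.89 in glomus-like, -0.85 in smooth muscle-like, -0.79 in fibroblast-like, -0.71 in macrophage-like and -0.38 in glia-like cells.

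B2m, the light chain of class I histocompatibility molecules, was higher in glomus-like (1.35), Schwann-like (1.17) and glia-like cells (0.91), but stood at 0.40 in the glia-like cells of cluster 5 alone, which left out 729 of the 1416 hypoxic cells, and at 0.91 in cluster 14 and 1.94 with the mitochondrial limit of 10% in glomus-like cells. It stood at 0.43 in fibroblast-like, 0.27 in macrophage-like and 0.22 in smooth muscle-like cells, and at -0.14 in endothelium-like cells. Ddit4, an inhibitor of growth signalling that hypoxia and glucocorticoids are both known to induce, was lower in hypoxia in all 7 classes, with -1.89 in fibroblast-like, -1.44 in endothelium-like, -1.29 in glia-like, -1.23 in macrophage-like, -1.14 in Schwann-like, -0.80 in glomus-like and -0.28 in smooth muscle-like cells (-1.39 at resolution 2.0). In macrophage-like cells the inflammatory genes Ccl3 and Tnf stood at -1.10 and -0.78 (-1.75 and -1.40 within cluster 12, while cluster 21, with 1.18 and 0.18, held 4 and 8 UMIs of Ccl3 and 8 and 8 of Tnf), and the haem-degrading enzyme gene Hmox1 at 0.69, or 0.12 within cluster 12.

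Fkbp5, Zbtb16, Klf15, Ddit4 and other genes known to respond to glucocorticoids had lower values in hypoxia in several classes. A list of such genes, assembled after some of its members had been seen lower, had median log2 values of -1.26 in glia-like, -1.05 in fibroblast-like, -0.77 in endothelium-like, -0.70 in smooth muscle-like, -0.59 in glomus-like, -0.56 in Schwann-like and -0.50 in macrophage-like cells, and 17 of 17 measured members were lower in glia-like and in fibroblast-like cells. The median over classes was -0.70 as measured, -0.67 after subtraction of the empty-droplet profile and -0.74 with cells thinned to 1000 UMIs, which argues against free RNA and cell depth as the whole cause. Time of day at collection stays open. The absolute gap between genes that peak with the clock gene Dbp and those opposed to it was 0.730 in the median over classes, Schwann-like cells left out. That lies between the bounds set for either reading. The list medians were 0.48 and -0.52 in endothelium-like, 0.27 and -0.70 in fibroblast-like, 0.50 and -0.24 in smooth muscle-like and 0.55 and -0.18 in macrophage-like cells. They did not part in this direction in glia-like (-0.53 and -0.39) or glomus-like cells (-0.032 and 0.037). Lower glucocorticoid signalling under hypoxia may be involved as a hypothesis, but with 1 library per condition it cannot be told apart from the hour or the handling of the animals, and its members were in part chosen because they were low.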
